A study of Homo sapiens with 221 samples.

How the data were processed

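Gene expression was measured in human B cells on Affymetrix U133 Plus 2.0 arrays, on which a gene is read by 1 or more sets of short probes. Per the labels, the cells were peripheral lymphocytes, positive for CD19 in normal samples and for CD19 and CD5 in samples of chronic lymphocytic leukemia (CLL), a cancer of mature B cells. Total RNA was extracted with Trizol, purified on RNeasy columns and labelled with biotin, per the labels' protocols. How the cells were isolated, and how they were handled before lysis, was not given in the sources used here.

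The values used were probe set intensities on a linear scale, deposited by the authors for 54675 probe sets on 221 arrays. The authors had processed them with RMA, which corrects background, quantile-normalizes arrays and summarizes probes, per the submitters' processing notes. Its version, and whether all arrays were normalized together, were not given in the sources used here. The deposited intensities ran from 7.81 to 46897 and the array medians from 90 to 125. RMA itself yields log2 values, so the linear scale was inferred from the values, and log2 was taken before any test. All columns were mapped to samples, and 0 arrays held the same values as another. RMA values carry no count or detection flag, so the number of arrays limits the precision.

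Gene symbols came from the platform's annotation table. It gave 1 symbol for 41097 probe sets and several for 1801, and 11777 were unnamed here. Of the probe sets with 1 symbol, 41043 matched a current gene by Entrez number. For the donors' privacy, 35 genes of the sex chromosomes, on 59 probe sets, were left out before any test. Only probe sets with 1 symbol were used. Each of the 19740 genes was represented by its probe set with the highest mean over the arrays of that experiment, which was the same probe set in both experiments for 18800 genes. Probe sets of a gene can disagree, and other probe sets are given for the named genes where they differ in sign.

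The arrays formed 2 experiments, analysed apart. A cohort held 24 normal and 179 CLL arrays. A culture experiment held 18 arrays from 3 normal and 3 CLL donors, each with an untreated culture and cultures labelled treated1 and treated2. Per the labels' protocols, treatment was with 5 and 50 ng/ml of Wnt3a for 48 hours, and which label is which dose was not given. The labels number the cohort arrays but do not say that each came from another person, so p-values measure the spread between these arrays.

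Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment. In the cohort a gene passed at an adjusted p under 0.05 and a change of at least 2-fold. In the culture experiment it passed at an adjusted p under 0.05. The Wnt3a contrasts were fitted on all 18 arrays together, without the donor. The untreated cultures of both cell kinds were compared on their own 6 arrays. A second Wnt3a fit had the donor as a block. The pairing came from the sample titles, which give the 3 cultures of a donor the same number. The deviations from the group means of the 18 pairs of arrays from the same donor correlated with a median r of 0.691 over genes, against -0.312 for 36 pairs from other donors of the same cell kind. Of the same-donor pairs 16 had an r over 0.1, and 1 array lay closer to another donor than to its own.

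Also fixed were 22 gene lists: 6 of the Wnt pathway with 141 measured members, canonical Wnt targets, CLL markers, B lineage genes, markers of 7 other cell types, and 6 cell programmes. Each was tested against all other genes with camera at a preset correlation of 0.01, then with an estimated one, and with fry. Members passing were counted with the adjustment over all genes and also adjusted over the list alone. In the cohort the counts adjusted over the list alone equalled those over all genes in every list. The genes named in the text were, for the cohort, the 10 highest and 10 lowest by log2 change among those passing, up to 4 passing members of each list, and 15 fixed Wnt and CLL genes. For Wnt3a they were up to 5 per direction and contrast by the blocked fit, and 11 fixed target genes. For the untreated cultures they were the 5 highest and 5 lowest. Immunoglobulin, T cell receptor and HLA genes were not named. The groups, tests, gene lists, naming rule and alternatives were choices made before the data were examined, except where the text says otherwise. TCF7 and WNT3, both fixed, had no probe set with 1 symbol and were not analysed here.

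RNA quality was read from the 3' minus 5' log2 signal of the GAPDH and ACTB control probe sets, compared with a two-sided permutation test of 100000 resamples, or an exact one where a group had under 10 arrays. Labelling batches were found from the control probe set for dap, a bacterial transcript that can be added to RNA before labelling. Its log2 intensity lay above 7 on 31 cohort arrays and below it on 172, of which 20 were normal and 152 CLL, and this split was made after the data were seen. The labels name no batch.

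The procedure was tested on simulated data drawn from the real means and spreads of the 19740 genes, with known changes in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. On the adjusted p alone, the cohort design recovered 91%, 100% and 100% of them. For the mean of both doses in CLL cells the shares were 19.4%, 74.6% and 100% without the donor block, and 67.2%, 92.5% and 100% with it. For the untreated cultures they were 11.9%, 55.2% and 93.9%. The simulated noise was independent between genes, with 1 spread per gene for all groups and no labelling batch. Real arrays differ in these respects, so the shares may overstate what was detectable.

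Alternatives were a second quantile normalization, median centring, leaving out dim genes, the mean of all probe sets of a gene, drawing 24 CLL arrays, a trended robust variance, GAPDH signal or marker scores of other cell types as covariates, other thresholds, the donor block, leaving out each donor, the labelling batch, and leaving out the array nearer to another donor. The authors' collapsed tables, planned as one alternative, held probe sets with the values already in use and were incomplete as obtained, so they were not run.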

Results

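Gene expression in B cells from blood was profiled on 221 arrays. The cohort held 24 arrays of normal B cells and 179 of B cells from chronic lymphocytic leukemia (CLL). The culture experiment held 18 arrays, 3 for each of untreated, treated1 and treated2 cultures of normal and of CLL B cells, treated with Wnt3a, a secreted ligand of the Wnt signalling pathway, at 5 or 50 ng/ml for 48 hours. All values are log2 of the authors' RMA intensities, and the number of arrays limits their precision. In the cohort, genes are called higher or lower when they passed both the adjusted p and the 2-fold threshold.

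The first question, per the series' design, was how genes of the Wnt pathway are expressed in CLL. LEF1, a transcription factor that carries the Wnt signal in the nucleus, was 18.4-fold higher in CLL, at 11.62 ± 0.96 (SD, n = 179) against 7.42 ± 0.86 (SD, n = 24), a log2 change of 4.20 ± 0.20 (SE; limma, adjusted p = 3.31e-48). ROR1, a receptor for Wnt ligands, was 8.57-fold higher (3.10 ± 0.19 SE, adjusted p = 1.09e-35). CELSR1, a planar polarity cadherin, was 3.54-fold higher (1.82 ± 0.15 SE). The Wnt receptor FZD3 and the corepressor TLE4 were 2.20-fold and 2.19-fold higher (1.13 ± 0.18 and 1.13 ± 0.19 SE), and the corepressor TLE1 was lower, with a log2 change of -1.14 ± 0.29 (SE).

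These 6 genes, 5 higher and 1 lower, were those that passed among the measured members of the 6 Wnt pathway lists, while 40 passed the adjusted p without regard to fold. That last count was 59 with the labelling batch as a block, 70 within the arrays without and 13 within those with poly-A control signal, and 26 with 24 CLL arrays drawn. None of the 6 lists shifted as a whole by camera (adjusted p from 0.0765 for receptors to 0.684 for antagonists), and their medians lay between -0.02 and 0.10. No member passed both thresholds in limma among 17 ligands, 22 antagonists and 30 cytoplasmic transducers, of which 7, 4 and 13 had an unadjusted p under 0.05. In normal B cells 4 of the ligands, 2 of the antagonists and 25 of the transducers lay above the median gene level, as did 1 of 18 receptors. Most ligands, antagonists and receptors were thus dim, which limits what these counts show. The ligand WNT10A had a change of 0.94 ± 0.15 (SE, adjusted p = 1.71e-08), short of 2-fold, and 0.42 (adjusted p = 0.548) within the arrays with poly-A control signal. WNT5A had one of 0.38 ± 0.15 (SE, adjusted p = 0.0401). CTNNB1, the gene of beta-catenin, had a change of -0.33 ± 0.14 (SE, adjusted p = 0.0593) and the receptor FZD6 one of -0.39 ± 0.20 (SE, adjusted p = 0.131). For CTNNB1 the adjusted p was 0.00121 with the labelling batch as a block, at -0.31. Its change was -0.36 within the arrays without and -0.005 (adjusted p = 0.989) within those with poly-A control signal. The 3 probe sets of CTNNB1 ran from -1.14 to -0.09, so the size of its change depends on the probe set. FZD6 turned in sign between the batches, from -0.59 (adjusted p = 0.000375) without to 0.78 (adjusted p = 0.453) with poly-A control signal, and the difference passed (interaction adjusted p = 0.0135).

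Among 28 canonical Wnt target genes 2 were higher and 2 lower. LEF1 and TCF4 (1.09 ± 0.12 SE) were higher, MYC, a growth-promoting transcription factor, was 5.27-fold lower (-2.40 ± 0.21 SE, adjusted p = 3.41e-21), and JUN was lower (-1.20 ± 0.27 SE). AXIN2, a negative regulator induced by canonical Wnt signalling in many cell types, did not pass, at 0.42 ± 0.26 (SE, adjusted p = 0.22), and its probe sets went down to -0.06. CCND1 and CCND2, which encode D-type cyclins, had changes of 0.28 ± 0.07 and 0.95 ± 0.14 (SE), below 2-fold, though CCND2 passed with the GAPDH covariate (1.10) and with 24 CLL arrays drawn (1.02). The list did not shift as a whole (median 0.07, adjusted p = 0.174), and 12 of its members lay above the median gene level in normal B cells.

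With the mean of all probe sets of each gene, 2 Wnt pathway genes passed, LEF1 (2.78) and ROR1 (2.35). The 3 probe sets of LEF1 ran from 0.74 to 4.20. Within the 31 arrays with poly-A control signal, where 4 normal and 27 CLL arrays could be compared, LEF1 was higher by 3.24, ROR1 by 2.54, CELSR1 by 1.38 and TLE4 by 1.29, and so was LGR6 by 1.80, named after its values were seen, whereas FZD3 (1.77, adjusted p = 0.0644) and TLE1 (-0.61, adjusted p = 0.564) did not pass. Within the arrays without that signal all 6 passed, together with WNT10A (1.04), and LEF1 was higher by 4.40, and with the batch as a block by 4.21.

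**Figure D1:**
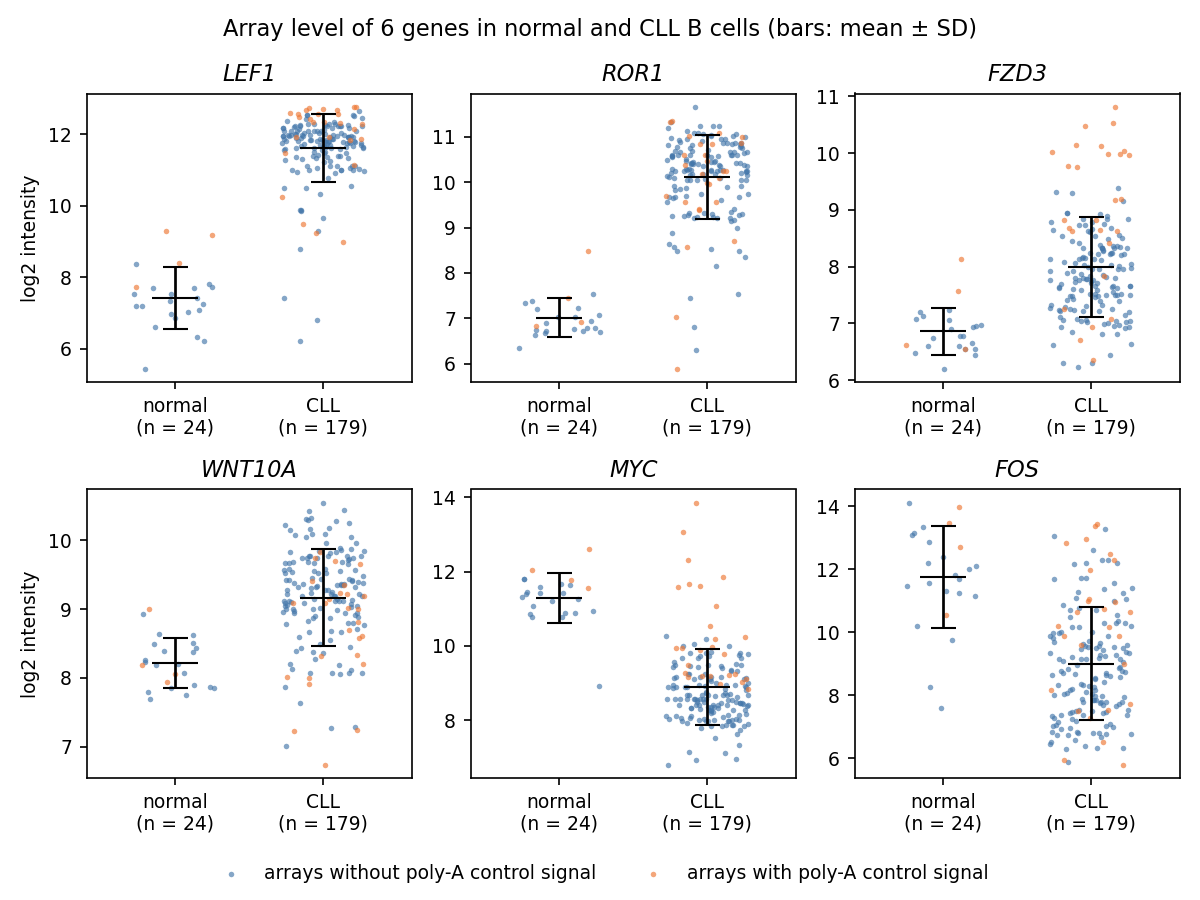
Log2 intensity of 6 genes on each cohort array, with normal and CLL B cells on the horizontal axis, 1 point per array coloured by labelling batch, and bars for mean ± SD. LEF1 averaged 7.42 in normal and 11.62 in CLL arrays, while MYC averaged 11.29 and 8.90.

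Across all genes, 531 of 19740 passed between CLL and normal B cells, 264 higher and 267 lower, and 5760 passed the adjusted p alone. The highest were ADTRP (49.9-fold, 5.64 ± 0.29 SE), the lipid transporter gene ABCA6 (36.8-fold, 5.20 ± 0.22 SE), LEF1, the immunoglobulin receptor gene PIGR (4.11 ± 0.21 SE), CCDC88A (4.003 ± 0.18 SE), the matrix proteoglycan gene FMOD (3.38 ± 0.29 SE), ROR1, TGFBI (3.07 ± 0.26 SE), ARHGAP44 (3.02 ± 0.26 SE) and the myeloid calprotectin gene S100A8 (2.86 ± 0.46 SE). The lowest were TSPAN13 (-4.25 ± 0.35 SE), JCHAIN, the joining chain of secreted antibodies (-4.04 ± 0.48 SE), CSGALNACT1 (-3.69 ± 0.30 SE), MLIP (-3.56 ± 0.36 SE), the immediate early genes NR4A2 (-3.40 ± 0.37 SE) and RGS1 (-3.18 ± 0.41 SE), PTPRK (-3.17 ± 0.25 SE), EBF1, a B lineage transcription factor (-3.15 ± 0.21 SE), TSPYL5 (-3.05 ± 0.22 SE) and the desmosomal gene DSP (-2.99 ± 0.15 SE). The probe set used for MLIP is of a type that can match several transcripts, and its other probe set had 0.22. The change thus cannot be assigned to MLIP itself. The probe sets of RGS1 ran from -3.18 to -0.08, those of CSGALNACT1 from -3.69 to -0.39 and those of PIGR from 0.71 to 4.11.

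Of the 531 genes, 515 (97%) had the same sign within both labelling batches. Among these, DSP had -2.65 on arrays without and -4.72 on arrays with poly-A control signal (limma interaction adjusted p = 2.17e-05). PIGR had 4.40 and 2.71 (limma interaction adjusted p = 0.0182). S100A8 was not among the 515, with 3.48 on arrays without and -0.19 on arrays with poly-A control signal. Within the arrays with that signal MYC (-1.69, adjusted p = 0.0963), JUN, JCHAIN, BANK1, CD24, CD38, BCL2, BCL2A1, BMF, CD83, OAS1, IFI44L, BCL11B, GZMK, FGFBP2, GZMA, PRF1, GNLY, HBB, HBD and PPBP did not pass either. With 4 normal arrays in that batch, some of these had changes there as large as over all arrays or nearly so, among them JUN (-1.24), OAS1 (1.27), IFI44L (-1.75), GZMK (1.89) and GZMA (1.99). The split between higher and lower genes moved from 49.7% higher to 60.9% with GAPDH signal as a covariate, and to 63.4% within the arrays with poly-A control signal. The fit takes 1 spread per gene for both groups. Its SE and p-values are thus too small for genes that vary more among the fewer normal arrays. DSP had an SD of 1.65 in normal and 0.46 in CLL arrays, S100A8 3.19 and 1.96, and IL6 1.645 and 0.76. The interaction tests also rest on 4 normal arrays in the smaller batch.

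Of 16 measured CLL marker genes 12 were higher and 0 lower (median 1.62, camera adjusted p = 3.58e-26, and adjusted p = 7.53e-05 with an estimated correlation). Besides ABCA6, LEF1, FMOD and ROR1 they included CD5, which was 4.01-fold higher (2.004 ± 0.13 SE). The labels name CD5 only for the CLL cells, so CD5 was part of how they were described. FCER2, the gene of CD23, had a change of 0.61 ± 0.25 (SE, adjusted p = 0.053) and did not pass, and with the labelling batch as a block 0.58 (adjusted p = 0.00993), short of 2-fold.

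Of 25 B lineage and B cell receptor signalling genes 7 were lower and 1 higher (median -0.22, adjusted p = 2.6e-07, and adjusted p = 0.0565 with an estimated correlation). EBF1, the adaptor gene BANK1 (-1.79 ± 0.19 SE) and the complement receptor gene CR1 (-1.39 ± 0.12 SE) were lower, and CD24 was higher (1.52 ± 0.19 SE). Of 10 plasma cell markers JCHAIN and CD38 (-1.30 ± 0.12 SE) were lower (list median -0.53, adjusted p = 5.44e-07, and adjusted p = 0.000392 with an estimated correlation).

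Of 23 immediate early and handling stress genes, which many cells switch on within minutes of stimulation or handling, 11 were lower and 0 higher (median -0.98, adjusted p = 1.06e-14, and adjusted p = 0.0331 with an estimated correlation, or 0.0821 with the labelling batch as a block). NR4A2, RGS1, FOS (-2.75 ± 0.38 SE) and CD69 (-2.36 ± 0.34 SE) were the furthest down. The median was -0.92 on arrays without and -1.28 on arrays with poly-A control signal. In the second batch FOS (-2.69), NR4A2 (-2.49), RGS1 (-2.34) and CD69 (-0.86) did not pass.

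Of 16 T cell markers 8 were higher and 0 lower (median 1.08, adjusted p = 1.51e-14, and adjusted p = 0.0247 with an estimated correlation, or 0.0821 with the labelling batch as a block), among them LCK (1.93 ± 0.15 SE), CD2 (1.89 ± 0.17 SE), BCL11B (1.59 ± 0.24 SE) and GZMK (1.45 ± 0.18 SE). The 3 probe sets of BCL11B ran from 0.02 to 1.59, and their mean had 0.93, short of 2-fold. Of 12 natural killer cell markers 6 were higher (median 1.09, adjusted p = 2.6e-07, and adjusted p = 0.127 with an estimated correlation), led by FGFBP2 (2.11 ± 0.30 SE), GZMA (1.998 ± 0.27 SE), PRF1 (1.78 ± 0.23 SE) and GNLY (1.70 ± 0.28 SE). Of 14 monocyte markers 9 were higher (median 1.23, adjusted p = 0.00168, and adjusted p = 0.591 with an estimated correlation), with S100A8, LYZ (2.42 ± 0.44 SE), S100A9 (1.80 ± 0.42 SE) and FCN1 (1.69 ± 0.40 SE) in front.

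The monocyte median was 1.47 on arrays without and 0.08 on arrays with poly-A control signal. On the latter LYZ (-0.27), S100A9 (-0.11) and FCN1 (-0.24) had the opposite sign and did not pass. The T cell medians were 1.01 and 1.14, and those of natural killer cells 1.05 and 1.34. Platelet PPBP (1.34 ± 0.42 SE) and the globin genes HBB (1.70 ± 0.46 SE, with 1 probe set at -0.006) and HBD (1.22 ± 0.36 SE) were higher too, as 1 of 12 platelet and 2 of 7 erythroid markers, with list medians of 0.23 and 0.33 and adjusted p of 0.325 and 0.128. With the marker scores of other cell types as covariates, which are built from these markers, CD2, BCL11B, GZMK, FGFBP2, GZMA, PRF1, GNLY, LYZ, S100A9, FCN1, PPBP, HBB and HBD did not pass. Of 10 neutrophil markers 0 passed in limma, 5 had an unadjusted p under 0.05, and the median was 0.12.

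The remaining lists held few genes that passed. Of 15 BCL2 family genes BCL2, which blocks apoptosis (1.28 ± 0.19 SE), and BMF, which promotes it (1.12 ± 0.10 SE), were higher and BCL2A1 was lower (-1.19 ± 0.27 SE). BCL2 had 0.50 with the mean of all probe sets, which ran from -0.22 to 1.28, and BCL2A1 -0.84 with the GAPDH covariate, both short of 2-fold. Of 22 NF-kB and inflammatory genes TRAF1 was higher (1.24 ± 0.11 SE), and CD83 (-1.97 ± 0.18 SE) and IL6 (-1.92 ± 0.19 SE) were lower. IL6 had -1.575 on arrays without and -3.64 on arrays with poly-A control signal (limma interaction adjusted p = 0.00123). Of 20 interferon response genes OAS1 was higher (1.19 ± 0.18 SE) and IFI44L lower (-1.33 ± 0.31 SE). Their medians were 0.04, 0.03 and -0.003. Of 24 proliferation genes 0 passed in limma (median -0.01, adjusted p = 0.555), and 6 were higher and 6 lower at an unadjusted p under 0.05. Of 13 cholesterol synthesis genes SC5D alone was lower (-1.001 ± 0.17 SE), and its other probe set had 0.28. SC5D fell short of 2-fold with the mean of its probe sets (-0.36), with the GAPDH covariate (-0.76), within the arrays with poly-A control signal (-0.41), with 24 CLL arrays drawn and with the batch as a block (-0.97 in both). That list had a median of -0.42 (adjusted p = 0.000901, and adjusted p = 0.0392 with an estimated correlation).

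**Figure D2:**
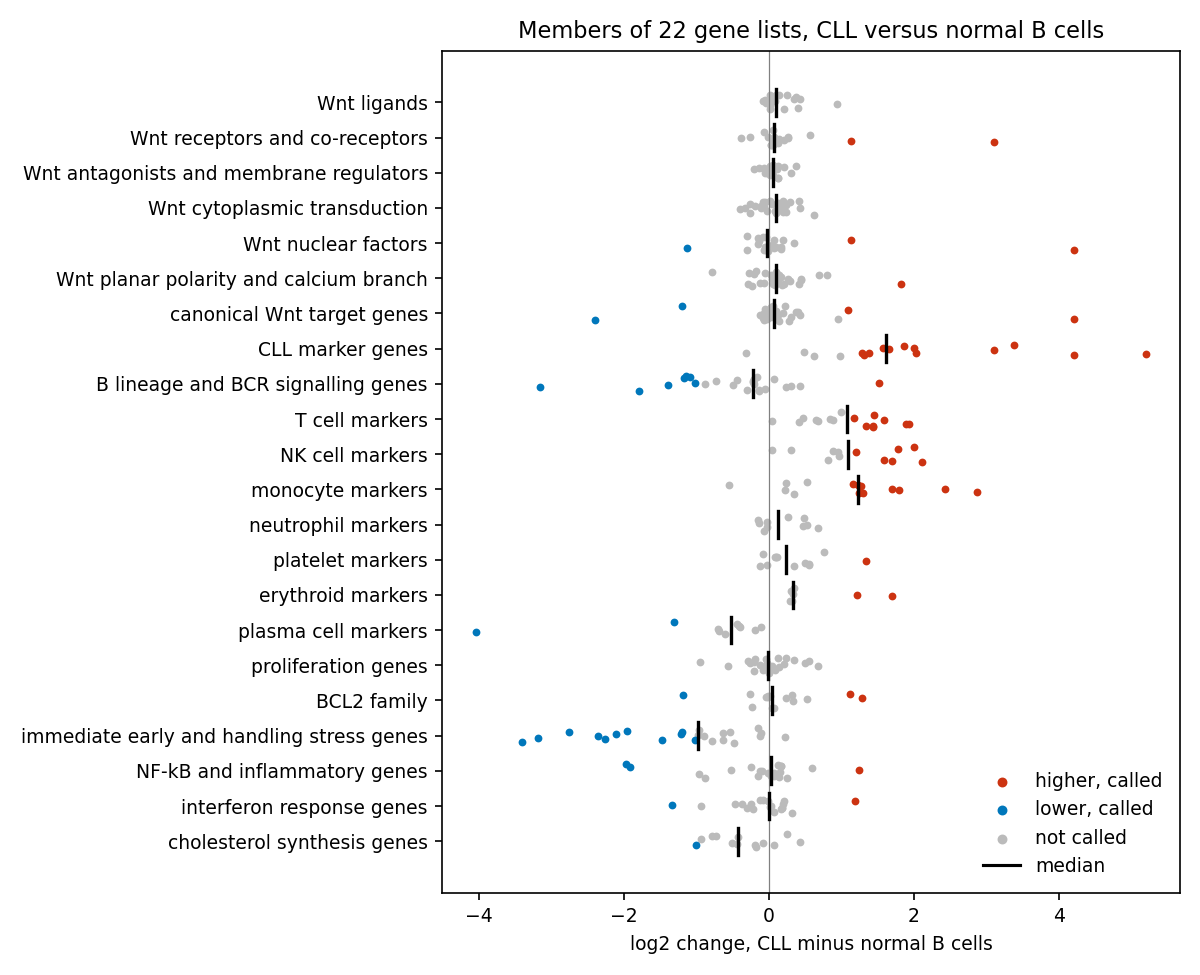
Log2 change of CLL minus normal B cells (horizontal axis) of each measured member of the 22 gene lists, 1 point per gene, coloured by whether it passed, with a bar at each list's median. Medians ran from -0.98 for immediate early genes to 1.62 for CLL markers.

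The 3' minus 5' log2 signal of GAPDH, which grows as RNA is degraded, was 0.384 ± 0.293 (SD) in CLL and 0.199 ± 0.130 (SD) in normal arrays, a difference of 0.185 (permutation p = 0.00289). On arrays without poly-A control signal it was 0.267 (permutation p = 4e-05), and on arrays with it -0.273 (exact permutation p = 0.00404). For ACTB the difference was 0.030 over all arrays (permutation p = 0.777), 0.115 on arrays without (permutation p = 0.0935) and -0.299 on arrays with poly-A control signal (exact permutation p = 0.0571). For both controls the sign thus differed between the labelling batches, so the value over all arrays mixes opposite differences.

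The second question was which genes respond to Wnt3a. At the mean of both doses, no gene passed in normal or in CLL B cells, and 0 genes differed in their response between them (limma, 3 donors each). At an unadjusted p under 0.05 there were 0.897% of the 19740 genes in normal cells, 2.665% (526 genes) in CLL cells and 2.356% (465 genes) for the difference. Without any response a share of about 0.05 of the genes would be expected there, and each of these lay below it. With the donor as a block the counts were 826, 2318 and 2501, again with 0 passing. The blocked count in normal cells lay below that share, and those in CLL cells and for the difference lay above it. Other choices of which culture to call untreated gave up to 3648 genes in normal and 3173 in CLL cells with the block. Exceeding that share thus does not mark a response. The target gene AXIN2 had a log2 change of -0.29 ± 0.25 (SE, n = 3) in normal and 0.17 ± 0.25 (SE, n = 3) in CLL cells, LEF1 changes of -0.16 and -0.15 (± 0.18 SE), and ZNRF3, a membrane regulator of Wnt receptors, changes of -0.02 and 0.22 (± 0.15 SE). NKD1 had -0.26 and 0.09 (± 0.14 SE), RNF43 -0.12 and 0.17 (± 0.14 SE), MYC 0.04 and -0.24 (± 0.33 SE), and CCND1 0.11 and 0.19 (± 0.17 SE). LGR5, TNFRSF19 and SP5 lay between -0.12 and 0.11. All had adjusted p of at least 0.988 in both cell kinds. With the donor as a block the smallest adjusted p of these genes was 0.977 in normal and 0.416 in CLL cells, the latter for MYC (-0.24 ± 0.11 SE, unadjusted limma p = 0.0389), and NKD1 had an unadjusted limma p = 0.0142 in normal cells. By donor, CCND1 was above 0 in 3 of 3 of both kinds and ZNRF3 in 3 of 3 CLL donors, while MYC and LEF1 were above 0 in 0 of 3 CLL donors and AXIN2 and NKD1 in 0 of 3 normal donors. Of these target genes ZNRF3 and SP5 were the dimmest, with group means of 4.74 to 4.97 and 5.39 to 5.55. The difference in response was 0.46 ± 0.35 (SE) for AXIN2 and 0.35 ± 0.20 (SE) for NKD1, with adjusted p of 0.952, or of 0.433 and 0.363 with the donor block (unadjusted limma p of 0.0791 and 0.0192).

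As a list, the 28 canonical Wnt targets had medians of 0.02 in normal and 0.04 in CLL cells, the latter -0.15 without dim genes (camera adjusted p of 0.779 and 0.723). At the mean of both doses, the genes with the smallest p in the blocked fit had changes below 2-fold within each cell kind. In normal cells they included RFC3 (0.50 ± 0.12 SE), CLOCK (0.54 ± 0.14 SE), PLPPR4 (-0.54 ± 0.11 SE) and the Wnt receptor gene FZD1 (-0.40 ± 0.09 SE), with SE of that fit. In CLL cells they included PCGEM1 (0.49 ± 0.10 SE), ELOVL6, a fatty acid elongase (0.48 ± 0.10 SE), ZNF431 (-0.92 ± 0.17 SE) and UFM1 (-0.56 ± 0.125 SE), again with SE of the blocked fit. ZNF431 had -1.14 for the difference in response and -1.04 for treated1 in CLL cells, over 2-fold, with adjusted p of 0.363 and 0.183 in the blocked fit.

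Single dose labels gave the same count of 0 passing genes. At an unadjusted p under 0.05 there were 0.699% of the 19740 genes for treated1, 0.963% for treated2 and 0.623% between them in normal cells. In CLL cells there were 5.248% (1036 genes), 0.9524% (188 genes) and 2.806% (554 genes). Only treated1 in CLL cells exceeded a share of 0.05. This fit leaves the spread between donors in its error and cannot be read against that share. With the donor block the counts, in the same order, were 548, 892, 461, 3520, 774 and 1591. Of these, treated1 and the contrast between the dose labels in CLL cells exceeded that share, which alone does not mark a response. With the donor block, other choices of the untreated culture were run only for the mean of both doses. For treated1 in CLL cells that blocked fit had 2599 genes at an adjusted p under 0.25, none of them under 0.05, and 527 after a second quantile normalization. The blocked fit passed 2 genes between treated2 and treated1 in CLL cells, SHTN1 (0.95 ± 0.13 SE, adjusted p = 0.0403) and SSPN-AS1 (-0.74 ± 0.11 SE, adjusted p = 0.043). In the blocked fit neither passed with a second quantile normalization (adjusted p of 0.0646 and 0.0935) or without the array nearer to another donor (adjusted p of 0.05225 for both). Both are too dim to be tested once dim genes are left out.

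Interferon response genes, antiviral genes such as IFIT1 and MX1, stood higher after Wnt3a in CLL cells as a list. All 20 measured members had a positive change, with a median of 1.01 (camera adjusted p = 5.98e-09), but with an estimated correlation the adjusted p was 0.8. IFI44L (1.94 ± 1 SE) and IFIT1 (1.93 ± 1.01 SE) were the largest, with adjusted p of 0.988, and 0 members passed over all genes or adjusted over the list alone, or 18 over the list alone with the donor block. The list's medians per CLL donor were -0.02, 0.05 and 2.80, and those of the normal donors ran from 0.004 to 0.17. Without CLL replicate 2 the median was -0.01. By dose label the medians were 0.71 for treated1 and 1.25 for treated2, a difference of 0.55 (adjusted p of 0.0243, 1.26e-18 and 0.00119, and of 0.737, 0.873 and 0.658 with an estimated correlation). The difference from normal cells was 0.90 (adjusted p = 0.000846, and adjusted p = 0.751 with an estimated correlation).

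At treated1 in CLL cells the Wnt ligands (median 0.16, adjusted p = 0.0478) and B lineage genes (median -0.13, adjusted p = 0.0338) also passed by camera, each with an adjusted p = 0.737 with an estimated correlation. The Wnt ligands had an adjusted p = 0.0629 with the donor block, and the B lineage median was 0.05 after a second quantile normalization. With the donor block camera also passed lists whose medians stayed within 0.25 of 0. At the mean of both doses these were immediate early genes (0.07) and cholesterol synthesis genes (0.14) in normal cells, and natural killer cell markers (-0.19), B lineage genes (-0.13, or 0.01 after a second quantile normalization) and the planar polarity branch (-0.10) in CLL cells. For the difference in response they were natural killer cell markers (-0.24), cholesterol synthesis genes (-0.21), Wnt antagonists (0.19) and B lineage genes (-0.13, or 0.02 after a second quantile normalization). For treated2 alone they were the BCL2 family in normal cells (0.09) and natural killer cell markers in CLL cells (-0.16). Their adjusted p ran from 0.0116 to 0.0498, and from 0.387 to 0.896 with an estimated correlation.

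**Figure D3:**
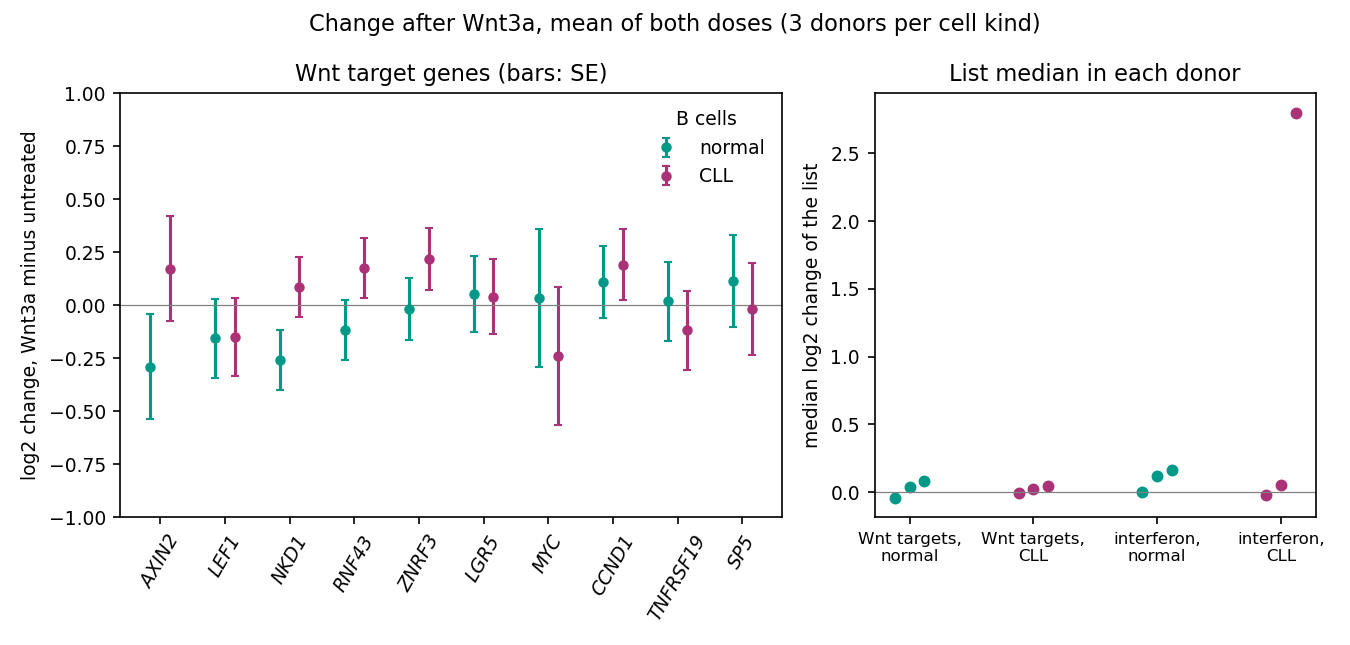
Log2 change after Wnt3a, mean of both doses, for 10 target genes in normal and CLL B cells (left, points with SE bars, 3 donors each), and median log2 change of the canonical Wnt target and interferon lists in each donor (right). The interferon median was 2.80 in 1 CLL donor and at most 0.17 in the other donors of both cell kinds.

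The untreated cultures allowed the first comparison to be made again, in 3 CLL against 3 normal donors. There 850 genes passed in limma, 540 higher and 310 lower in CLL, 495 of them at 2-fold or more. LEF1 was 20.1-fold higher (12.33 ± 0.35 against 8.0 ± 0.31, SD, n = 3, a log2 change of 4.33 ± 0.21 SE, limma adjusted p = 9.54e-06). The highest were GIMAP7, a lymphocyte GTPase gene (5.35 ± 0.35 SE), SPP1, the gene of osteopontin (5.03 ± 0.45 SE), SELENOP (4.36 ± 0.69 SE), LEF1 and the secreted ribonuclease gene RNASE1 (4.06 ± 0.42 SE). Markers of T cells, natural killer cells and monocytes were also higher in these CLL cultures, so the higher genes need not be those of B cells. The lowest were JCHAIN (-4.63 ± 0.57 SE), BMS1P20 (-4.01 ± 0.26 SE), MLIP (-3.78 ± 0.16 SE), the chemokine gene CXCL8 (-3.49 ± 0.61 SE) and the ecto-enzyme gene NT5E (-3.28 ± 0.24 SE). The probe sets for BMS1P20 and MLIP can match several transcripts, so their changes cannot be assigned to these genes themselves. With a trended robust variance SELENOP, CXCL8 and JCHAIN did not pass (adjusted p of 0.144, 0.152 and 0.0543).

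ROR1 was higher here too (1.41 ± 0.24 SE, adjusted p = 0.00689), as were TLE4 (1.40 ± 0.17 SE) and CD5 (1.18 ± 0.17 SE), and TLE1 was lower (-0.79 ± 0.15 SE), though TLE1 did not pass without normal replicate 3 (-0.67). CELSR1 (0.85 ± 0.30 SE, adjusted p = 0.173), FZD3 (0.32 ± 0.14 SE, adjusted p = 0.311), WNT10A (-0.10 ± 0.14 SE) and MYC (-0.97 ± 0.27 SE, adjusted p = 0.09) did not pass, though MYC did without CLL replicate 2 (-1.27). FZD3, CD5 and TLE1 were read here by other probe sets than in the cohort. Of the 10 highest and 10 lowest cohort genes, TSPAN13 (-2.99 ± 0.74 SE, adjusted p = 0.0517) and RGS1 (-1.33 ± 0.46 SE, adjusted p = 0.178) did not pass after culture, nor did PIGR (-0.20), ARHGAP44 (0.57) and NR4A2 (-0.26), which were read by other probe sets. TSPAN13 did pass without CLL replicate 1 (-4.10) and with dim genes left out (-2.99). With a trended robust variance CSGALNACT1, S100A8 and CCDC88A did not pass (limma adjusted p of 0.188, 0.181 and 0.0941), and the first 2 also failed without some single donors. Of the 531 cohort genes 459 (86.4%) had the same sign after culture. Passing in both comparisons were 150 higher genes, against 7.22 for independent lists, and 88 lower genes, against 4.19, while 4 passed in opposite directions. On the same probe sets SPP1 and RNASE1 had cohort changes of -0.07 and 0.04. Over genes, which are not independent replicates, the changes correlated with r = 0.48. The labels do not say whether the donors of the cultures were also in the cohort.

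In the counts of list members after culture, the number in parentheses is the count adjusted over the list alone. CLL markers were higher in 11 of 16 (12), with a median of 1.37 and an adjusted p = 0.0213 with an estimated correlation. T cell markers were higher in 15 of 16 (16), natural killer cell markers in 10 of 12 (10) and monocyte markers in 10 of 14 (13), with medians of 1.86, 2.25 and 1.74 and adjusted p of 0.0528, 0.0528 and 0.0548 with an estimated correlation. Proliferation genes were lower in 14 of 24 (17, median -0.80), among them RRM2 (-2.70 ± 0.19 SE) and TOP2A (-1.33 ± 0.23 SE), picked as examples after their values were seen, with an adjusted p = 0.0528 with an estimated correlation. B lineage genes were lower in 12 of 25 (13, median -0.39, adjusted p = 0.251 with an estimated correlation).

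Interferon genes were lower in 7 of 20 (10, median -0.54) and NF-kB genes in 6 of 22 (10, median -0.33). Cholesterol synthesis genes were lower in 3 of 13 (7, median -0.44), plasma cell markers in 3 of 10 (4, median -0.37) and immediate early genes in 2 of 23 (5, median -0.23). By camera all 5 passed, with adjusted p of 1.02e-07, 3.75e-05, 9.5e-06, 0.00184 and 0.0148, but with an estimated correlation these were 0.305, 0.0528, 0.305, 0.324 and 0.305. The Wnt receptors, nuclear factors and canonical targets held 1, 3 and 4 passing members, and the other 4 Wnt pathway lists 0 in limma, with between 1 and 12 members at an unadjusted p under 0.05. None of these 7 lists shifted as a whole (adjusted p from 0.192 to 0.932). Of the BCL2 family 2 were higher and 2 lower, of the neutrophil markers 2 were higher, of the platelet markers 1 was lower, and of the erythroid markers 0 passed, even at an unadjusted p under 0.05 (adjusted p of these lists from 0.18 to 0.685).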

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

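The tests on the labelling batches, on immediate early genes, on interferon genes and on the donors within splits below were chosen only after the results were seen, while those on T cells and GAPDH signal for the Wnt genes were planned.

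The Wnt pathway genes higher in CLL were weighed first, because markers of T cells, which themselves express LEF1, were higher in the same arrays. The tables argue against leftover T cells as the whole cause: the T cell markers, of which 8 of 16 lie above the median gene level in normal B cells and 0 belong to another list, had a median of 1.08 against 4.20 for LEF1, which kept 3.99 with the marker scores of other cell types as covariates. Labelling batch was argued against too, with 7 passing within the larger batch. Under the GAPDH covariate 5 of the 6 genes were left, where TLE1 had -0.86, which met the planned rule against RNA quality. That fit held no labelling batch, while the GAPDH difference was 0.267 in the larger batch and -0.273 in the smaller. The covariate thus cannot exclude RNA quality. All 6 genes kept their sign in both batches while the GAPDH difference turned, with LEF1 and ROR1 higher in both. This argues against RNA quality, as GAPDH reads it, as their whole cause. FZD3 and TLE1 did not pass in the smaller batch, which held 4 normal arrays. Other splits of the arrays do not reach the overall count, since only the real split of 100 gave 531 genes or more and the highest other gave 24. A difference between CLL and normal B cells themselves may underlie LEF1 and ROR1, as a hypothesis found and tested on the same data.

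Immediate early genes were lower in CLL, 11 of 23, of which 22 lie above the median level in normal B cells and 1 belongs to another list. The tables argue against the labelling batch, since the median was -0.917 in the batch nearer to 0. With GAPDH signal as a covariate the median was -0.881, which met the rule set against RNA quality. That fit held no labelling batch, so it cannot exclude RNA quality. Within the batches the list's median was -0.917 and -1.28, where the GAPDH difference was 0.267 and -0.273. The same direction under opposite GAPDH differences argues against RNA quality, as GAPDH reads it, as the whole cause. In the smaller batch the list's mean level was 9.9 ± 1.11 (SD, n = 27) in CLL and 11.3 ± 1.05 (SD, n = 4) in normal arrays, so few normal arrays carry this. Handling before lysis and a difference of the cells themselves cannot be told apart, because the labels give no handling for any array. Between the untreated cultures the median was -0.232, which may reflect a difference in handling that culture removed or a difference between the cells that culture narrowed.

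A test of the difference between cell kinds picked out the interferon response genes after Wnt3a, whose change was 0.902 larger in CLL than in normal cells by camera at the preset correlation, with an adjusted p = 0.751 with an estimated one. A response shared by the CLL donors was argued against, since the middle CLL donor had 0.0517, within the range of the normal donors, and the list's shift came from 1 donor, where all 20 genes were higher at treated2 than at treated1. More monocytes in those treated cultures were argued against as well, with their markers, of which 12 of 14 lie above the median level in normal B cells, at 0.115 ± 0.314 (SD over genes) where the interferon genes reached 3.53. What set that donor's cultures apart may be Wnt3a itself, another stimulus or handling, and 1 donor leaves this open.

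At the mean of both Wnt3a doses the immediate early list's median was above 0 in all normal and below 0 in all CLL donors, with middle values of 0.162 and -0.0456, but at treated2 alone both kinds had donors on either side, the CLL value nearest to 0 was -0.00163, and camera on the difference did not pass (median -0.105, adjusted p = 0.245, or 0.157 with the donor block).

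The CLL minus normal change differed between the labelling batches, by an interaction term, for 4039 genes, and the changes within the 2 batches correlated with r = 0.58 over genes.

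Control probe sets outside the comparisons carried a poly-A control signal on 31 cohort arrays, 4 normal and 27 CLL, whose 90th percentile of log2 intensity ran from 9.87 to 10.11, against 8.99 to 9.64 on the others. Whether this difference in scale underlay the interaction above was not tested.

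For the untreated cultures, 1 of the 10 splits of 6 arrays reached 850 genes, the real one, and the highest other gave 1. For the 6 single Wnt3a contrasts and for the difference in response the real and the highest other count were both 0, and all 10 splits tied. With 10 splits a share under 0.05 is out of reach. For the mean of both doses the real count was 0, which all 84 splits reach whatever the data, so this comparison says nothing about chance. The highest other count was 0.826% of the genes in normal and 16.3%, or 3218 genes, in CLL cells. In both kinds that split set the cultures of 1 donor against those of the others, and splits with all 3 donors in each group gave at most 0 genes, so the large counts followed the donors. Among the 27 ways to call 1 culture of each donor untreated, with the donor as a block, the real 826 normal genes at an unadjusted p under 0.05 were reached by 12, with 3648 as the highest other, and the real 2318 CLL genes by 3, with 3173.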

How the results depend on the processing

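The alternatives on labelling batches and on the array nearer to another donor were added after the data were seen. The cohort count of 531 stayed within 1.5 times, from 389 to 625, under every alternative but the 1.5-fold threshold, which gave 1451 genes, 784 higher and 667 lower. With the batch as a block 521 of the 531 genes passed, and 489 and 230 within the batches without and with poly-A control signal. For Wnt pathway genes the count of 6 became 2 with the mean of all probe sets and 11 at 1.5-fold, and was 5 to 7 otherwise.

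All Wnt3a counts at an adjusted p under 0.05 stayed at 0 under every alternative, except that the replicate block gave 2 genes between treated2 and treated1 in CLL cells. With the replicate block, and list tests aside, no other call changed. An adjusted p under 0.25 left them at 0 without the block, but with it gave 2599 genes for treated1 and 4 for treated2 against treated1 in CLL cells. Without the array nearer to another donor the counts stayed 0 at 0.05, while at 0.25 the blocked fit had 4774 genes for treated1, 14 for treated2 against treated1 and 1425 for the mean of both doses in CLL cells, 1692 for treated2 and 3 for the mean in normal cells, and 5009 for the difference in response. Leaving out each donor gave 0 in each Wnt3a contrast and 575 to 819 genes between the untreated cultures, against 850 with all, and an adjusted p under 0.25 gave 2354 there.

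The GAPDH difference of 0.185 was 0.030 with ACTB probe sets. Within the arrays without and with poly-A control signal it was 0.267 and -0.273, and for ACTB 0.115 and -0.299. Within the arrays with that signal S100A8 (-0.195), LYZ (-0.273), S100A9 (-0.106), FCN1 (-0.240) and PPBP (-0.448) turned in sign. With the marker scores of other cell types as covariates, which the model builds from the same markers, BCL11B (-0.236), GZMK (-0.00227) and the medians of T cell (-0.165) and monocyte markers (-0.166) turned. Leaving out each donor gave interferon medians from -0.0123, without CLL replicate 2, to 1.45 in CLL cells, and from -0.0213 to 1.36 for the difference in response. The B lineage median for treated1 in CLL cells was 0.050 after a second quantile normalization, with or without the replicate block. For the covariates and the omitted donor the setting's construction shows the cause, and for the other changes the cause was not tested.

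Of single cohort genes, 639 gene and setting pairs kept their direction and side of the threshold, 50 fell short of it, 4 newly passed it, 7 turned in sign and 1 moved. Between the untreated cultures these were 572, 38, 6, 0 and 15. For Wnt3a, 2195 kept them, 83 moved and 2 newly passed. The authors' collapsed tables were not run as an alternative. The number of arrays, 4 normal ones in the smaller batch and 3 donors per cultured group, limits what was detectable, and no signal over background was available.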

Other observations

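The tests in this part were chosen after the cohort results were seen, except for the covariate fit, which was planned.

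Some single genes, picked after their values were seen, had larger changes between the untreated cultures than in the cohort. MRC1 (3.46 ± 0.46 SE), CD36 (3.41 ± 0.33 SE) and IL7R (3.82 ± 0.35 SE) were higher in CLL cultures and had 1.10 ± 0.27, 0.94 ± 0.32 and 1.33 ± 0.23 (SE) in the cohort, in the same direction. These differences between experiments were not tested, nor was which cells in the cultures gave them. In the other direction the chemokine gene CCL22, chosen in the same way, was 8.53-fold lower after culture (-3.09 ± 0.25 SE) and did not pass in the cohort (0.07).

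Of 12 correlations with the mean T cell marker level, computed within the labelling batches over CLL arrays with 100000 resamples, that of CD3E, itself one of these markers, with CD3E left out of the mean, had r = 0.93 and rho = 0.905 (permutation p = 1e-05 each, the smallest they can give, adjusted p = 3e-05) over the arrays without poly-A control signal, and r = 0.926 without the 2 arrays farthest from the median. Over the 27 arrays with that signal CD3E had r = 0.811 (permutation p = 1e-05, the smallest it can give, adjusted p = 3e-05), rho = 0.752 (permutation p = 2e-05) and r = 0.712 without 2 arrays. Without that signal LEF1 had r = 0.181 (permutation p = 0.0254, adjusted p = 0.0435) and rho = 0.0962 (permutation p = 0.239), and r = 0.184 without those 2 arrays. Over the 27 arrays with that signal LEF1 had r = -0.353 (permutation p = 0.0716, adjusted p = 0.0981), rho = -0.287 (permutation p = 0.146) and r = -0.298 without 2 arrays. ROR1 had r = -0.197 (permutation p = 0.0149, adjusted p = 0.0319), rho = -0.174 (permutation p = 0.0327) and r = -0.182 without 2 arrays in the larger batch. In the smaller it had r = -0.352 (permutation p = 0.0736, adjusted p = 0.0981), rho = -0.531 (permutation p = 0.00474) and r = -0.389 without 2 arrays. FZD3 had r = -0.459 (permutation p = 0.0159, adjusted p = 0.0319), rho = -0.443 (permutation p = 0.0217) and r = -0.537 without 2 arrays in the smaller batch, and r = -0.0104 (permutation p = 0.9) and rho = 0.0397 (permutation p = 0.627) in the larger. The r of LEF1 differed in sign between the batches. No difference in r, between genes or batches, was tested.

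With the marker scores of other cell types as covariates 625 cohort genes passed, 265 higher and 360 lower, of which 469 were among the 531. FOS then had -3.97, MYC -3.03 and CD5 2.10, and the natural killer cell markers GZMA and PRF1 had 0.21 and 0.34.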
